A study of Homo sapiens with 15 samples.

How the data were processed

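RNA sequencing measured polyadenylated RNA of human cells in 15 libraries, 3 in each of 5 groups. The groups were endometrial stromal fibroblasts (ESF), decidualized ESF (dESF), dESF after co-culture with extravillous trophoblasts, extravillous trophoblasts (EVT), and EVT after co-culture with dESF. The fibroblasts were primary cells and the EVT were derived from trophoblast stem cells, per the labels, whereas the title of the series calls the EVT primary. Libraries were made with a standard Illumina mRNA kit, per the labels' protocols. Reads were assigned to genes with featureCounts on genome build GRCh38, per the submitters' processing notes. The aligner, the annotation, the strand setting and the software versions are not given in the sources used here.

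The deposited values were TPM, length-scaled transcript abundances, 1 column per library, as the name of the deposited table says. The table held 21378 genes by Ensembl identifier, and each column summed to between 999768.1 and 999893.7. Symbols came from the gene name table supplied with the data, in which 1531 identifiers had none. XIST and Y-linked genes (47 identifiers) were left out of every step, since the fibroblasts came from people. Of the remaining genes, 3633 were at 0 in every library.

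Low TPM values of a gene were whole multiples of 1 step in each library, so the reads behind the values could be recovered. All 17698 detected genes gave whole reads in every library, within a tolerance of 0.001 reads. On simulated tables the recovered reads were exact for 99.84% of the detected genes. The recovered totals were 14.22 to 22.74 M reads per library (median 18.4), with 15.65 to 20.22 M for ESF and 16.92 to 19.07 M for dESF. Co-cultured dESF had 17.72 to 22.74 M, EVT 16.95 to 18.28 M and co-cultured EVT 14.22 to 19.08 M. Replicate libraries differed more than counting error alone would give, by a chi-square of 4.22 to 12.6 per degree of freedom. Counting intervals and floors of 3 reads, printed where a group had few reads, cover counting error only, at a level of 95%.

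The gene lengths behind the TPM values were not those of the genes. Over 12914 genes with enough reads, the length followed from reads and TPM, and no gene's length equalled its own genomic span in the GENCODE release 29 annotation (GRCh38). Of 5551 lengths above 30000 bp, 59.8% equalled the span of another gene, and 6.8% did so after a shift of 1 to 50 bp. TPM therefore does not compare genes with each other, and the added constant of 1 weighs differently on each gene. It compares 1 gene between libraries only up to 1 scale factor per library, since the same lengths enter the sum that scales each library. Levels of named genes are therefore given as recovered reads scaled to equal library totals (RPM).

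The main test was limma on log2(TPM + 1) with a mean-variance trend, for 10290 genes with a TPM of at least 1 in at least 3 libraries. All 15 libraries entered 1 fit with 1 coefficient per group and 10 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(TPM + 1) scale understate the change of genes with low TPM. The 5 comparisons were dESF with ESF, co-cultured with single-cultured dESF, co-cultured with single-cultured EVT, the difference between both co-culture responses, and EVT with dESF. The test, the comparisons, 32 gene lists, the naming rule and all alternatives except those said to be added were chosen before the data were examined.

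Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 31 lists tested, camera called 14 for dESF with ESF, 16 for co-cultured dESF, 9 for co-cultured EVT, 12 for the difference of the responses and 15 for EVT with dESF. With a correlation estimated from the data, 3, 0, 1, 0 and 4 of these calls held.

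Genes were named by a fixed rule. For the first 3 comparisons it took the 10 largest rises and the 10 largest falls among called genes without overlap of the libraries (chance gives no overlap for 10% of genes) and with a mean TPM of at least 5 in the higher group. For the difference of the responses it took 5 each way without the overlap condition. Genes without a symbol, clones, and mitochondrial, ribosomal and histone genes were not taken this way. From each described list up to 4 called members with the largest change were named. PRL, IGFBP1, FOXO1, HAND2 and WNT4 were reported for the dESF comparisons, and HLA-G, ITGA1, ITGA5, ITGA6 and MMP2 for the EVT comparisons, whatever their values. Reads of near-identical or overlapping genes could have been split in counting, and the strand setting is unknown, so values of such genes are uncertain. List members such as TIMP1, TIMP3, IRF1, TAP1, TAP2 and TGFB3 had 0 reads in every library and entered no test. Whether counting lost their reads was not tested, so the lists may lack members that the cells express.

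The RNA of the partner cell in a co-cultured library was estimated as a share. It was the median, over genes at a mean TPM of at least 50 in the partner and at most 0.1 in ESF (for EVT RNA) or in EVT (for dESF RNA), of the TPM relative to the partner's level. On simulated mixtures with 1% of EVT RNA the estimate for dESF was 1.017%. Overlaps of called genes were set beside the number from independent lists, and results sharing dESF libraries beside 100 simulations of unchanged groups.

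The tests were tried on simulated data for the real genes, 50 genes at each fold. In each simulation 200 genes changed, in both directions, at a dispersion (spread beyond counting error) of 0.01. Far more genes were called in the real data, where the scaling of the libraries moved the split of directions. The shares below therefore hold for these simulations and are no error rates of the real calls. For dESF with ESF, where 9615 simulated genes passed the filter, 16% of genes changed 1.25-fold, 70% at 1.5-fold and 98% at 2-fold were recovered, and 6.6% of calls were false. At 1.5-fold, 68% were recovered in each co-culture comparison and 64% for EVT with dESF, with 5.4%, 7.3% and 5.6% of calls false. For the difference of the responses, 22% were recovered at 1.5-fold and 90% at 2-fold, with 3.6% false calls.

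The alternatives were other pseudocounts, other filters, median-of-ratios and quantile scaling, robust variance moderation, a fit of only the groups compared, a fold threshold, the replicate number as a block, and leaving out each library. The list tests were also run with an estimated correlation and with fry, and the partner shares with other gene sets. Added after the data had been seen were limma voom on the recovered reads (14054 genes with at least 10 reads in at least 3 libraries), with total or median-of-ratios library sizes, a share from recovered reads, a share from genes at most at 0.1 TPM in dESF as well as ESF, the dESF libraries split between the comparisons, and leaving out genes within reach of 3 times the partner's share. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.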

Results

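The libraries covered both cell types of an implantation site in culture, the endometrial stromal fibroblast and the invading extravillous trophoblast, alone and together. Each of the 5 groups had 3 libraries, with 14.22 to 22.74 M recovered reads per library. Between 8546 and 8954 genes had a TPM of at least 1 in each library. Levels are recovered reads scaled to equal library totals (RPM), as mean ± SD of 3 libraries, and changes are log2 fold changes of TPM + 1 ± SE from the limma fit, with its adjusted p. Nothing in the labels says that replicates are separate cultures or donors, so the p-values measure only the spread between samples, which may be technical.

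The first comparison set both cell types in single culture side by side. EVT had far more epithelial keratin than dESF, and KRT8 stood at 6350 ± 309 RPM against 25.7 ± 1.06, a log2 fold change of 7.87 ± 0.12 (adjusted p = 7.141e-16). HLA-G, the class I molecule that marks invading trophoblast, was at 1076 ± 57.1 in EVT and 0.797 ± 0.395 in dESF, a change of 7.82 ± 0.10 (adjusted p = 1.859e-16). CGA, which encodes the alpha chain of chorionic gonadotropin, was the most abundant of these, with 59740 ± 2371 RPM against 11.2 ± 1.74. Transcripts of collagen VI and vimentin went the other way. COL6A3 stood at 2455 ± 135 RPM in dESF and 0.887 ± 0.105 in EVT, a change of -9.35 ± 0.05 (adjusted p = 6.059e-19), and VIM at 3044 ± 144 and 0.164 ± 0.284. Among the integrins, ITGA5 was higher in EVT by 1.82 ± 0.05 (adjusted p = 6.238e-13). Lower in EVT were ITGA1, with a change of -0.41 ± 0.05 (adjusted p = 3.536e-06), ITGA6, with -0.48 ± 0.06 (adjusted p = 9.755e-06), and the gelatinase gene MMP2, with -0.49 ± 0.07 (adjusted p = 1.137e-05).

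Of 24 tested genes of fibroblast and mesenchymal identity, 21 were lower and 2 higher in EVT (camera adjusted p = 2.42e-07), with PDGFRB and COL6A2 next to COL6A3 and VIM. Steroid receptors and uterine HOX genes were lower for 10 and higher for 2 of 12 (camera adjusted p = 0.001526), led by HOXD11, HOXD10, MEIS1 and AR. Trophoblast identity genes were higher for 20 and lower for 1 of 21 (camera adjusted p = 1.532e-07), with KRT8, KRT7, GCM1 and KRT18 in front. All 21 tested proliferation genes were higher in EVT (camera adjusted p = 1.01e-06), among them CCNB1, CDC20, RRM2 and E2F1. These 4 calls held with an estimated correlation. EVT markers were higher for 22 and lower for 4 of 26, with NOTUM, LAIR2, HLA-G and TAC3 in front (adjusted p = 0.1036 with an estimated correlation). Syncytiotrophoblast markers were higher for 23 and lower for 1 of 24 (adjusted p = 0.1154 with an estimated correlation), led by HSD3B1, CGA, CGB8 and CGB5. Genes of cholesterol synthesis and uptake, with HMGCS1, SQLE, LDLR and INSIG1, were higher for 19 and lower for 0 of 20 (adjusted p = 0.07985 with an estimated correlation). Stress response genes of the endoplasmic reticulum, with TRIB3, PHGDH, ATF3 and DNAJB9, were all higher, 22 of 22 (adjusted p = 0.1306 with an estimated correlation). In all, 8910 of 10290 genes differed, 4549 higher and 4361 lower in EVT. Counts adjusted over the list alone were equal to these for every list of this comparison.

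**Figure D1:**
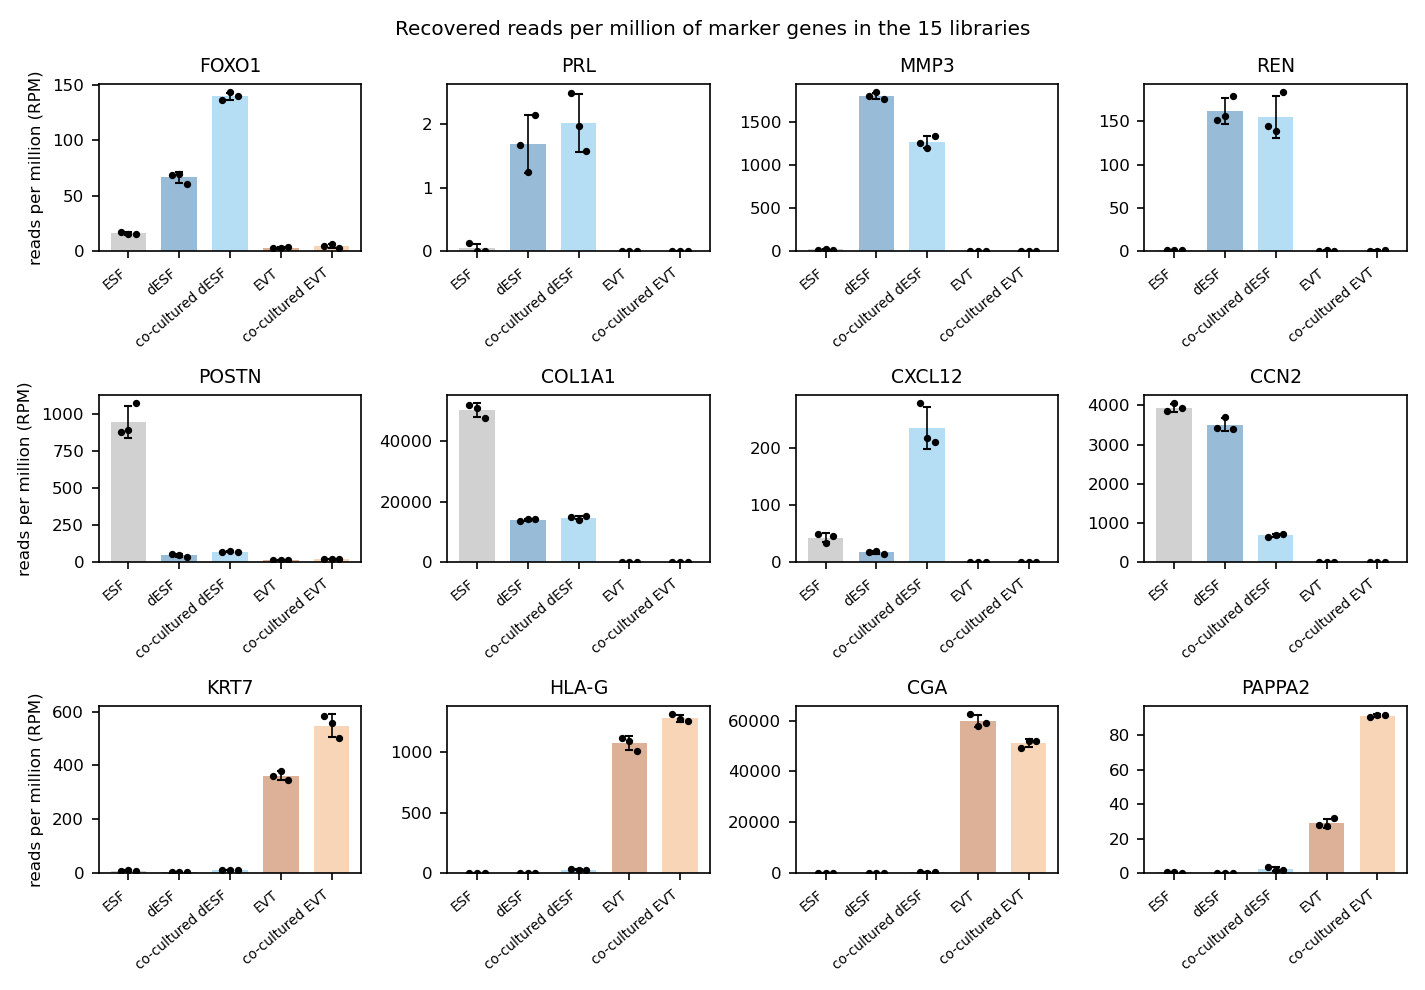
Recovered RPM (vertical axis, linear) of 12 marker genes in the 5 groups, with bars for the mean, error bars for the SD and dots for the 3 libraries of each group. MMP3 rose from 19.8 in ESF to 1809 in dESF, CCN2 was at 689 in co-cultured and 3508 in single-cultured dESF, and HLA-G and CGA were near the axis in the fibroblast groups.

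The comparison of dESF with ESF asked which genes changed as the fibroblasts decidualized. Among the genes that the naming rule took, a stromelysin and a renin gene rose most on the log2(TPM + 1) scale. MMP3 (ENSG00000149968, GRCh38 chromosome 11, 102835801 to 102843803), which encodes a matrix-degrading protease, went from 19.8 ± 2.29 to 1809 ± 35.9 RPM, a change of 6.18 ± 0.06 (adjusted p = 1.04e-15). REN, which starts the angiotensin cascade, went from 1.60 ± 0.166 to 162 ± 15.1, a change of 6.08 ± 0.28 (adjusted p = 2.976e-09). The complement gene C3 rose from 5.09 ± 2.56 to 106 ± 4.39 (adjusted p = 8.591e-08). The matrix protein gene POSTN fell from 947 ± 108 to 48.3 ± 9.98, a change of -4.07 ± 0.11 (adjusted p = 3.673e-11), and THBS2 fell from 1742 ± 134 to 147 ± 10.1. Transcription factors of the immediate early response fell as well, with KLF2 down from 26.0 ± 2.02 to 1.12 ± 0.0466, a change of -4.59 ± 0.21 (adjusted p = 2.976e-09), and EGR2 at -4.17 ± 0.36 (adjusted p = 1.106e-06).

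The other large rises were those of CST1, CST2, CXCL1, IL13RA2, EPHB6 and ALDH1L1, with log2 fold changes of 3.12 to 3.75, and that of ENAM, on few reads. ENAM had 0, 0 and 5 reads in the ESF libraries and 20, 19 and 24 in dESF, and its change of 5.64 was 4.20 ± 0.75 under voom. CST2 had 0 reads in ESF and 51 in dESF, so it was at least 16.9-fold higher, and it shares sequence with CST1. COL15A1, ADM2, HSPB6, LRRN2, SYT7 and PRLR were the other large falls, with changes of -4.04 to -2.86. COL15A1 went from 56.9 ± 8.90 to 0.355 ± 0.188 RPM. LRRN2 had 60 reads in ESF and 2 in dESF, a ratio of 30.2 (95% counting interval 8.0 to 255). PRLR, the receptor of prolactin, went from 6.01 ± 0.280 to 0.569 ± 0.222.

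FOXO1, a transcription factor of the decidual program, rose from 16.2 ± 1.251 to 66.5 ± 4.77 RPM, by 1.85 ± 0.14 (adjusted p = 3.166e-07). HAND2, a progesterone-responsive factor, rose by 0.49 ± 0.06 (adjusted p = 4.607e-05). The secreted markers were scarce. PRL had 2 reads in all ESF libraries and 93 in dESF, a ratio of 46.2 (95% counting interval 12.4 to 388), and its TPM lay below the filter of the main test. The added limma voom test on reads gave PRL 5.15 ± 0.76 (adjusted p = 1.343e-06). IGFBP1 had 5 reads in ESF and 0 in dESF, too few for a test. WNT4, also below the filter, did not differ in the voom test (0.40 ± 0.51, adjusted p = 0.5514). Among 15 tested decidualization markers 7 rose and 2 fell, with FOXO1, MAOA and FKBP5 up and DKK1 down. As a list they did not stand apart from other genes (camera adjusted p = 0.5458). The split became 5 to 5 under median-of-ratios scaling, 12 to 3 of 23 under voom (0.2015), and 10 to 5 under voom with median-of-ratios library sizes, where the list was called (0.0448).

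Matrix genes made up the clearest fall. Of 22 tested collagen genes 16 fell and 2 rose (camera adjusted p = 5.233e-11). COL1A1, the main chain of type I collagen, dropped from 50110 ± 2299 to 14000.0 ± 240 RPM, with a change of -1.92 ± 0.07 (adjusted p = 3.869e-10), and COL5A3 and COL6A1 fell by 2.14 and 1.77. Fibroblast identity genes fell for 14 and rose for 5 of 24 (camera adjusted p = 2.403e-07), led by POSTN, COL1A1, COL6A1 and COL6A2. Immediate early genes fell for 14 and rose for 2 of 19 (camera adjusted p = 2.024e-09), with KLF4 and EGR3 behind KLF2 and EGR2. These 3 calls held with an estimated correlation. Adhesive matrix genes such as ELN and FN1 fell for 17 and rose for 7 of 28 (adjusted p = 0.1017 with an estimated correlation). FN1, which encodes fibronectin, dropped from 34320 ± 1248 to 9453 ± 472 RPM.

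Proteases of the matrix went both ways, 8 up and 10 down of 22 (camera adjusted p = 0.247), with a median change of -0.06 and a mean of 0.25, and under voom 11 rose and 8 fell. MMP3, MMP1 and MMP10 rose, and ADAM12 fell by 2.12 ± 0.07 (adjusted p = 1.706e-10). WNT pathway genes fell for 8 and rose for 2 of 14, with FZD7, SFRP1, DKK1 and RSPO3 down (adjusted p = 0.06957 with an estimated correlation). Of the TGF-beta responsive genes 10 of 20 fell and 5 rose (adjusted p = 0.2485 with an estimated correlation), and 13 of 21 fell and 3 rose under median-of-ratios scaling. ID1 and ID3, inhibitors of basic helix-loop-helix factors, rose by 2.96 and 1.39 while TGFBI and TGFBR1 fell. Stress response genes went both ways, 11 down and 8 up of 22 (adjusted p = 0.3746 with an estimated correlation). The largest changes on the log2(TPM + 1) scale were in PHGDH, ASNS, TRIB3 and PSAT1 (-2.75 to -1.44). That scale understated the fall of PSAT1, which had 2280, 2600 and 3290 reads in ESF and 296, 241 and 270 in dESF. Under median-of-ratios scaling 14 fell and 5 rose. Counts adjusted over the list alone were equal to those over all genes for each list of this comparison given so far.

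In all, 5138 genes changed with decidualization, 3573 up and 1565 down, and 309 of them at least 2-fold (112 up, 197 down). The split depended on the scaling. With median-of-ratios scaling 1877 rose and 2615 fell, with quantile scaling 2585 and 2029, with voom on reads 5406 and 1672, and with voom at median-of-ratios library sizes 2302 and 3274. The median of all genes was 0.096 on TPM as deposited, -0.012 with median-of-ratios scaling and 0.205 with voom, so small changes have no settled direction.

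The comparison of co-cultured with single-cultured dESF asked what trophoblasts did to the decidualized fibroblasts. The chemokine gene CXCL12 (chromosome 10, 44370165 to 44386493) rose from 17.3 ± 2.502 to 234 ± 37.2 RPM, by 3.69 ± 0.17 (adjusted p = 3.809e-09). ADGRL3, an adhesion receptor gene, rose by 3.42 ± 0.19 (adjusted p = 2.024e-08), from 5.61 ± 1.80 to 61.7 ± 5.23. CCN2, a target of TGF-beta and of mechanical tension, fell from 3508 ± 171 to 689 ± 39.8, a change of -2.37 ± 0.08 (adjusted p = 2.852e-10). The protease inhibitor gene SERPINE2 fell from 1895 ± 215 to 409 ± 31.4 (-2.14 ± 0.09, adjusted p = 1.041e-09). HK2, which starts glycolysis, fell from 116 ± 6.43 to 23.0 ± 0.499 (-1.99 ± 0.06, adjusted p = 1.7e-10). FIBIN, IL19, TNFSF4, NCAM1, HMCN1, HAS2 and SPSB1 were the other large falls, with changes of -2.52 to -2.10.

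The other large rises included genes of the trophoblast itself. HSD3B1, a steroidogenic enzyme gene, had 0 reads in single-cultured dESF and 629 in co-culture, at least 184-fold more. CGB8, a gonadotropin beta chain gene with near-identical copies, was at least 1160-fold higher, SLC30A2 at least 32.2-fold and KANK4, on 22 reads, at least 6.45-fold. NOTUM had 3 reads and 3057 reads, a ratio of 896 (95% counting interval 306 to 4350). CGA rose from 11.2 ± 1.74 to 366 ± 121 RPM (3.81 ± 0.16, adjusted p = 1.712e-09), and PHOSPHO1 and AIF1L rose by 3.88 and 3.62. Over 45 genes high in EVT and at most at 0.1 TPM in ESF, co-cultured dESF libraries held 0.892% ± 0.238 of the EVT level (median over genes, mean ± SD of 3 libraries). Single-cultured dESF held 0.0%, and 43 of the 45 genes were higher in co-culture (exact permutation p = 0.1, the smallest that 3 against 3 can give). MAOA, 1 of the 45, was expressed by single-cultured dESF (1.486 TPM) and was not higher in co-culture. The 37 genes at most at 0.1 TPM in dESF as well, a set chosen after the data had been seen, gave 0.948% ± 0.3. In co-cultured EVT the measure over 31 fibroblast genes was 0.0%.

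**Figure D2:**
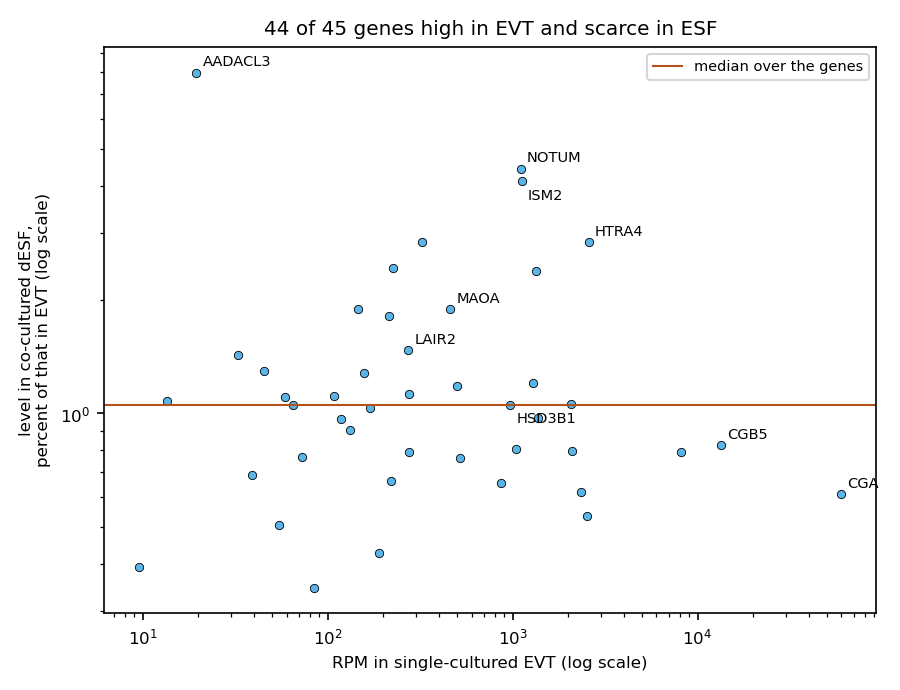
Level of the genes high in EVT and scarce in ESF, in co-cultured dESF, as a percent of the level in single-cultured EVT (vertical, log scale), against RPM in EVT (horizontal, log scale), 1 dot per gene and a line at the median of 1.05%. AADACL3 (7.97%), NOTUM (4.44%) and ISM2 (4.12%) lie farthest above the line, and RORC, at 0, is not drawn.

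Syncytiotrophoblast markers, led by HSD3B1, CGA, CGB8 and CGB5, rose for 15 and fell for 2 of 24 in co-cultured dESF, and for 18 and 2 adjusted over the list alone (adjusted p = 0.2108 with an estimated correlation). EVT markers rose for 14 and fell for 5 of 26, and 15 and 5 over the list alone, with NOTUM, HLA-G and LAIR2 up and SERPINE1 down (adjusted p = 0.3758 with an estimated correlation). That camera call (adjusted p = 0.04) was also lost under voom (0.3867), a pseudocount of 5 (0.333), a fit of only these groups (0.07624) and without dESF replicate 1 (0.05365). Trophoblast identity genes rose for 14 and fell for 3 of 21, with KRT8, KRT18 and KRT7 up and KRT19 down (adjusted p = 0.2108 with an estimated correlation). With quantile scaling 6 of these rose and 3 fell, and the camera call was lost at a pseudocount of 5 (0.1345). Genes within reach of 3 times the EVT share were left out in a setting added after the data had been seen. There 2 of 8 EVT markers rose and 5 fell, and 3 of 7 identity genes rose and 3 fell. Only genes with a higher mean TPM in co-culture could be left out this way, so falls stayed by construction. These counts therefore do not show that markers apart from EVT RNA mostly fell. HLA-G stood at 28.5 ± 5.88 RPM in co-cultured dESF.

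Genes of mesenchymal identity mostly rose. Of 24 tested, 16 rose and 2 fell, and 17 and 2 adjusted over the list alone (camera adjusted p = 0.0007416; adjusted p = 0.06446 with an estimated correlation). Of this list 2 genes were higher in EVT than in dESF. MFAP5 had 10916, 11021 and 10864 reads in the EVT libraries, 1, 0 and 0 in dESF and 217, 204 and 161 in co-cultured dESF. For MFAP5 a response of dESF was not separated from the EVT RNA. COL3A1 rose from 4212 ± 241 to 9000.0 ± 360 RPM, by 1.05 ± 0.05 (adjusted p = 8.301e-09), COL6A1 and FBLN1 rose by 0.89 and 0.88, and VIM fell by 0.75. Collagens rose for 13 and fell for 4 of 22 (adjusted p = 0.2313 with an estimated correlation), with COL14A1 up from 61.6 ± 2.13 to 713 ± 43.4. Steroid receptors and uterine HOX genes rose for 9 and fell for 1 of 12, and 10 and 1 over the list alone (adjusted p = 0.06446 with an estimated correlation). PGR, the progesterone receptor gene, went from 26.2 ± 2.48 to 60.9 ± 2.21 (1.15 ± 0.14, adjusted p = 3.487e-05), and HOXA11, MEIS1 and GATA2 rose by 0.69 to 0.71, though MEIS1 was not called at a pseudocount of 0.1 (adjusted p = 0.07035). FOXO1 rose again, to 140 ± 3.26 (1.02 ± 0.14, adjusted p = 8.797e-05), and HAND2 rose by 0.64 ± 0.06 (adjusted p = 7.078e-06). In the voom test PRL did not differ (0.27 ± 0.33, adjusted p = 0.5577) and WNT4 was higher (1.42 ± 0.41, adjusted p = 0.006288). IGFBP1 had 2 reads in co-culture. Of the 15 decidualization markers 7 rose and 5 fell, and 7 and 6 over the list alone with a median change of 0.15 and a test direction downward (camera adjusted p = 0.9605). IL15 rose and GADD45B and DIO2 fell.

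TGF-beta responsive genes fell for 11 and rose for 4 of 20, and 13 and 4 adjusted over the list alone (camera adjusted p = 9.774e-06; adjusted p = 0.07069 with an estimated correlation). SERPINE1 fell from 2152 ± 29.03 to 695 ± 24.8 RPM and INHBA, the activin A subunit gene, from 885 ± 12.5 to 285 ± 22.4, beside CCN2 and PMEPA1. Genes of hypoxia and glycolysis fell for 13 and rose for 3 of 25, and 13 and 4 over the list alone (adjusted p = 0.2108 with an estimated correlation), with HK2, ANGPTL4, STC2 and PFKFB4 in front. Integrins fell for 8 and rose for 4 of 15, and 9 and 4 over the list alone (adjusted p = 0.06446 with an estimated correlation). ITGA11 and ITGB5 fell while ITGB8 rose. ITGB4 rose from 0.403 ± 0.0232 to 1.67 ± 0.468 RPM, beside 124 ± 13.0 in EVT, within reach of 3 times the EVT share. Smooth muscle genes such as TPM1, SYNPO2 and ACTG2 fell for 9 and rose for 1 of 16, and 9 and 2 over the list alone (adjusted p = 0.2108 with an estimated correlation). ACTA2 was the exception, on few reads, with 27, 20 and 24 in the dESF libraries and 70, 75 and 78 in co-culture. TAGLN had 17555, 16284 and 18833 reads in the same dESF libraries. Whether counting lost reads of ACTA2 was not tested, so its level and change are uncertain. Interferon-stimulated genes, with IFI6, OAS2, EPSTI1 and IFIH1, rose for 10 and fell for 0 of 16, and 10 and 1 over the list alone (adjusted p = 0.2759 with an estimated correlation). Antigen presentation genes, with HLA-F, TAPBP, HLA-B and ERAP1, rose for 8 and fell for 1 of 15 (adjusted p = 0.2825 with an estimated correlation). The interferon, antigen presentation and integrin calls were lost at a TPM filter of 5 (camera adjusted p = 0.221, 0.08407 and 0.08407). Under voom on reads, at the preset correlation, they were kept (camera adjusted p = 0.0001558, 0.003892 and 0.000746).

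Co-culture changed 3628 genes of dESF, 2268 up and 1360 down, and 313 of them at least 2-fold (219 up, 94 down). Quantile scaling gave 1564 up and 2304 down. The other scalings gave 58.2% to 71.2% of the calls upward, beside 62.5% on TPM as deposited. Without genes within reach of the estimated EVT share 3558 genes were called.

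The comparison of co-cultured with single-cultured EVT asked what the fibroblasts did to the trophoblasts. Markers of the mature invasive trophoblast rose. HPGD, which degrades prostaglandins, went from 29.9 ± 1.87 to 110 ± 13.0 RPM, by 1.72 ± 0.09 (adjusted p = 6.628e-08). PAPPA2, a protease that frees insulin-like growth factors, went from 28.95 ± 2.46 to 91.4 ± 0.811 (1.27 ± 0.05, adjusted p = 7.639e-09). MCAM and SPON2 rose by 1.08 ± 0.09 (adjusted p = 3.011e-06) and 1.06 ± 0.09 (adjusted p = 4.175e-06). MMP2 rose from 2852 ± 120 to 4358 ± 225 (0.57 ± 0.07, adjusted p = 7.635e-05), ITGA5 by 0.42 ± 0.05 (adjusted p = 0.0001466) and ITGA1 by 0.34 ± 0.05 (adjusted p = 0.0003709). ITGA6 did not differ (-0.11 ± 0.06, adjusted p = 0.2486). HLA-G stood at 1283 ± 29.6 beside 1076 ± 57.1 (0.21 ± 0.10, adjusted p = 0.1671), a difference that passed at a pseudocount of 5 (adjusted p = 0.04068) and under voom (0.001271). Of 26 tested EVT markers 21 rose and 1 fell, and 22 and 1 adjusted over the list alone (camera adjusted p = 1.062e-20), a call that held with an estimated correlation (0.0141).

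**Figure D3:**
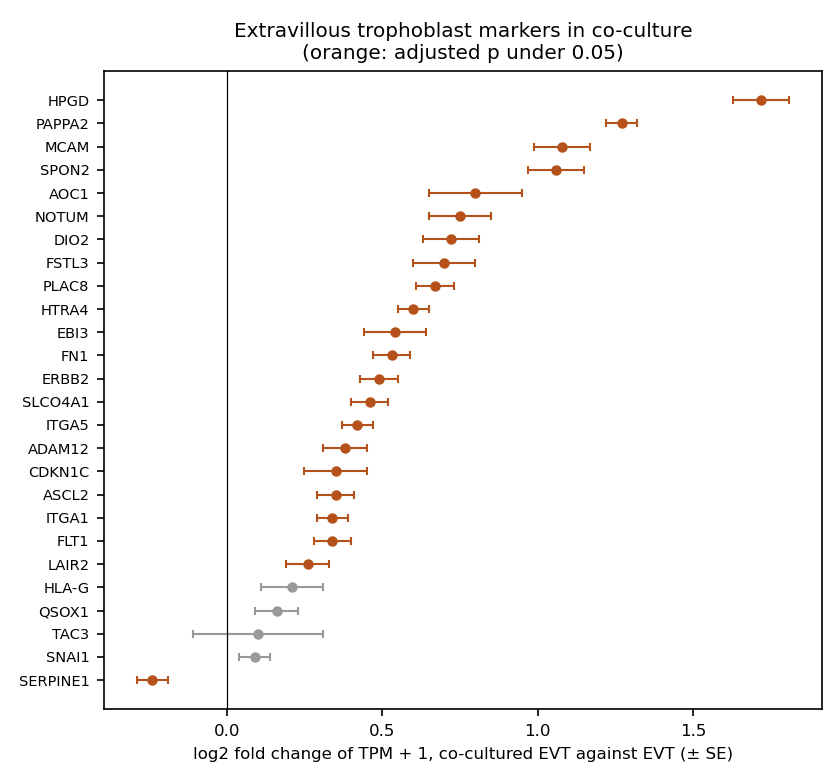
Log2 fold change of TPM + 1 in co-cultured against single-cultured EVT (horizontal) for 26 markers of extravillous trophoblast, 1 point per gene with its SE (n = 3 libraries per group), orange where the limma adjusted p was under 0.05. HPGD lies highest at 1.72, HLA-G at 0.21 is not among the called genes, and SERPINE1 is the marker that fell.

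STC1 (chromosome 8, 23841915 to 23854807), which encodes the hormone stanniocalcin, had the largest rise among the genes that the naming rule took. It went from 0.698 ± 0.183 to 6.89 ± 0.678 RPM (2.32 ± 0.13, adjusted p = 1.375e-07). The receptor kinase gene ALK went from 4.30 ± 0.348 to 25.5 ± 3.62 (2.06 ± 0.09, adjusted p = 2.647e-08), and ARNT2, CPS1 and SLC6A3 rose by 1.74, 1.53 and 1.48. FTCD and COL6A2 rose by 1.99 and 1.49 on fewer reads. TRIM47 and XAF1, at 1.59 and 0.653 RPM in co-culture, lost their calls in several settings. TRIM47 was not called without co-cultured EVT replicate 1 (adjusted p = 0.08621) or 3 (0.09668), nor XAF1 without EVT replicate 3 (0.06669) or co-cultured EVT replicate 2 (0.05824) or 3 (0.1152). ASNS, which makes asparagine, fell from 76.8 ± 1.42 to 34.6 ± 5.03 (-1.15 ± 0.10, adjusted p = 9.716e-06), and KISS1, which encodes kisspeptin, from 34.8 ± 2.60 to 17.4 ± 3.52 (-1.04 ± 0.20, adjusted p = 0.003066). At a pseudocount of 0.1 the adjusted p of KISS1 was 0.2363. HAP1 and TMEM37 fell by 1.41 and 1.55, and DPEP2, FUOM, CYP2C9, SLC15A2, DACH2 and GPR149 fell from levels under 10 RPM. DPEP2 and SLC15A2 were not called at a pseudocount of 0.1 (adjusted p = 0.06058 and 0.09248), nor FUOM under voom (0.0635).

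Genes of the insulin-like growth factor system rose for 7 and fell for 0 of 19, and 8 and 0 adjusted over the list alone (adjusted p = 0.2265 with an estimated correlation). PAPPA went from 494 ± 59.2 to 937 ± 74.6 RPM and HTRA1 from 26.8 ± 3.90 to 71.4 ± 3.77, next to STC1 and PAPPA2. Collagens rose for 8 and fell for 0 of 22, among them COL6A2, COL27A1, COL5A1 and COL4A1 (adjusted p = 0.1996 with an estimated correlation). COL5A1 was not called in a fit of only these groups (adjusted p = 0.08613). Proteases and inhibitors of the matrix rose for 8 and fell for 1 of 22, and 8 and 2 over the list alone (adjusted p = 0.3485 with an estimated correlation), with SERPINE2 and MMP11 beside HTRA1 and MMP2. MMP11 was not called without EVT replicate 1, 2 or 3 (adjusted p = 0.06087, 0.07516 and 0.07912) or co-cultured EVT replicate 1, 2 or 3 (0.06954, 0.06087 and 0.08203). Antigen presentation genes, with NLRC5, HLA-E, PSMB8 and HLA-F, rose for 8 and fell for 0 of 15, and 9 and 0 over the list alone (adjusted p = 0.2265 with an estimated correlation). NLRC5 was not called without EVT replicate 1 (adjusted p = 0.1103) or 2 (0.053) or co-cultured EVT replicate 3 (0.09061), at a pseudocount of 5 (0.0784) or in a fit of only these groups (0.1629), where PSMB8 was not called either (0.05829). Interferon-stimulated genes such as IFIH1, ISG15 and PARP9 rose for 5 and fell for 0 of 16, and 6 and 0 over the list alone (adjusted p = 0.3141 with an estimated correlation). At the preset correlation the interferon call was also lost at a TPM filter of 5 (camera adjusted p = 0.2739) but kept under voom (3.08e-05). Stress response genes, led by ASNS, PHGDH, TRIB3 and DDIT4, fell for 12 and rose for 2 of 22 (adjusted p = 0.3485 with an estimated correlation). Syncytiotrophoblast markers went both ways, with LEP and PAPPA up and KISS1 and HSD17B1 down. Of 24 tested 5 rose and 9 fell, and 5 and 12 over the list alone (camera adjusted p = 0.1943, and 0.007047 under voom).

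In all, 2130 genes of EVT changed in co-culture, 840 up and 1290 down, and 54 of them at least 2-fold (40 up, 14 down). Median-of-ratios scaling gave 1092 up and 777 down, quantile scaling 990 and 931, voom 1207 and 1118, and voom with median-of-ratios library sizes 1306 and 951. The direction of the majority was thus not settled.

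The difference between both responses asked which genes reacted differently in the fibroblast and in the trophoblast. STC1 fell in dESF from 116 ± 16.3 to 57.6 ± 6.93 RPM and rose in EVT, a difference of -3.35 ± 0.18 (adjusted p = 3.642e-08). SERPINE2 fell in dESF and rose in EVT from 170 ± 7.80 to 300 ± 18.5 (difference -2.80 ± 0.12, adjusted p = 8.544e-09). SPON2 did likewise, from 2855 ± 122 to 1064 ± 73.3 in dESF and from 21.1 ± 2.46 to 52.2 ± 3.54 in EVT (-2.52 ± 0.12, adjusted p = 2.077e-08). FIBIN and TNFSF4, at or near 0 reads in EVT, differed by -2.52 and -2.39. On the other side were HSD3B1, KANK4, PHOSPHO1, LY75-CD302 and CGA, with differences of 4.08 to 4.79, all of them genes with more reads in EVT than in single-cultured dESF. LY75-CD302 is a read-through of neighbouring genes and rested on 0.198 ± 0.142 RPM in co-cultured dESF.

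Genes of the insulin-like growth factor system had the lower response in dESF for 9 and the higher for 2 of 19 (adjusted p = 0.133 with an estimated correlation), with STC1, HTRA1, IRS1 and PAPPA in front. HTRA1 fell in dESF from 2830 ± 80.2 to 1350 ± 21.4 while it rose in EVT. TGF-beta responsive genes had the lower response in dESF for 10 and the higher for 3 of 20, and 11 and 4 adjusted over the list alone (adjusted p = 0.121 with an estimated correlation), led by CCN2, PMEPA1, INHBA and SERPINE1. PMEPA1, near 0 reads in EVT, was not called under voom (adjusted p = 0.7658). Genes of hypoxia and glycolysis split 12 to 6 of 25, and 14 to 6 over the list alone (adjusted p = 0.2394 with an estimated correlation), led by HK2, ANGPTL4, PFKFB4 and STC2. Syncytiotrophoblast markers had the higher response in dESF for 18 and the lower for 4 of 24 (adjusted p = 0.2394 with an estimated correlation), with HSD3B1, CGA, CGB8 and CGB5. In all, 3345 genes responded differently, 2222 higher and 1123 lower in dESF, and 399 by at least 2-fold. With median-of-ratios scaling the split was 1744 to 1387, with quantile scaling 1350 to 1710 and with voom at median-of-ratios library sizes 1633 to 1431.

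The responses of both cell types were set side by side. Of the genes called in both, 454 moved the same way, 260 up and 194 down, beside 185.1 and 170.5 from independent lists (Fisher's exact p = 4.364e-10 and 0.04308, across genes, which are not independent). Another 310 rose in dESF and fell in EVT (284.3 from independent lists, Fisher's exact p = 0.06705), and 160 fell in dESF and rose in EVT (111, Fisher's exact p = 6.862e-07). Across all tested genes the fold changes of both responses had a Pearson r of 0.033 and a Spearman rho of 0.048. These comparisons share no libraries. NOTUM, ISM2, AADACL3, HTRA4 and HPGD rose in both, but they are genes of EVT with 0 or few reads in single-cultured dESF, and a response of dESF was not separated from the EVT RNA in those libraries. CRABP2, which binds retinoic acid, rose in both, by at least 2-fold in dESF and outside the reach of 3 times the EVT share. CARD16 fell in both, by at least 2-fold in dESF. The genes named in this paragraph were chosen after their values were seen.

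The last comparison asked whether co-culture continued or turned back the changes of decidualization. CXCL12 fell by 1.35 with decidualization and rose by 3.69 in co-culture, and KLF4 fell from 16.02 ± 1.578 to 2.27 ± 0.3205 RPM and rose by 2.85 to 22.36 ± 1.553. PRLR fell by 2.86 and rose by 3.01, but it stood at 7.26 ± 0.390 RPM in co-cultured dESF and at 187 ± 21.6 in EVT, so a response of dESF was not separated from the EVT RNA. COL14A1, SFRP1 and THBS2 fell and rose likewise. On the log2 scale the rise was 273.9% of the fall for CXCL12, 191.7% for COL14A1 and 156.1% for SFRP1, thus past the ESF level. It was 50.8% for THBS2. Of the large decidualization changes, those of MMP3 and POSTN were undone by only 8.9% and 10.3%. COL14A1, KLF4 and SFRP1 were chosen after their values in co-culture were seen. Of the 1565 genes that fell with decidualization 675 rose in co-culture (43.1%, 344.9 from independent lists) and 231 fell further (14.8%, 206.8). Of the 3573 that rose, 782 fell in co-culture (21.9%, 472.2 from independent lists) and 450 rose further (12.6%, 787.5). FOXO1 and HAND2 were among the latter. Both comparisons use the dESF libraries, so a negative relation arises without any effect. The Pearson r of the fold changes across genes was -0.257 (-0.503 ± 0.0304 in simulations of unchanged groups), and the covariance was -0.046 (-0.009 ± 0.0008 in the simulations). Fold changes had the same sign for 42.9% of genes (33.3% in the simulations). With the 3 dESF libraries split 1 and 2 between the comparisons, so that none was in both, a test added after the data had been seen, 749 to 927 genes changed in opposite directions. These were 1.8 to 2.1 times the numbers from independent lists, with a Pearson r of -0.221 to -0.199.

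**Figure D4:**
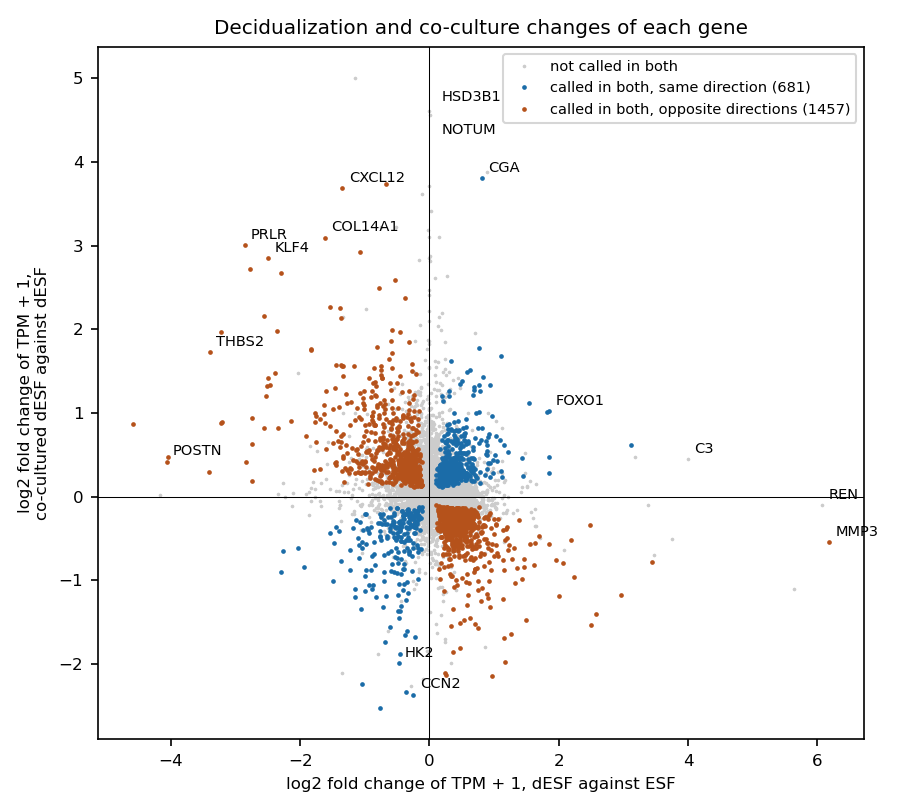
Log2 fold change of TPM + 1 of each tested gene in co-cultured against single-cultured dESF (vertical) and in dESF against ESF (horizontal), 1 dot per gene. Orange dots are the 1457 genes called in both with opposite directions, such as CXCL12 and COL14A1, and blue dots the 681 called in both with the same direction, such as FOXO1.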

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

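Genes whose response to co-culture differed between dESF and EVT were marked for a closer look because the difference itself was tested. That test and the count over other splits of the libraries were chosen before the result was seen.

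There were 3345 such genes, and the largest 5 each way are the genes named here, with log2 differences of the responses (dESF minus EVT, limma). STC1 had the largest negative difference, -3.35, since it fell in dESF and rose in EVT. SERPINE2 (-2.80) and SPON2 (-2.52) also moved in opposite directions. FIBIN (-2.52) fell in dESF and had 0 reads in both EVT groups, and TNFSF4 (-2.39) fell in dESF and was near 0 in EVT. HSD3B1 (4.79), CGA (4.08), PHOSPHO1 (4.47) and KANK4 (4.76) were read in co-cultured dESF at a small percentage of their EVT level, and a response of dESF was not separated from the EVT RNA in those libraries (0.892% of the EVT level). LY75-CD302 (4.45) had under 1 RPM in every group. Fitted differences of genes at 0 reads in a group depend on the added constant and are no bounds.

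Of 100 splits that regrouped the libraries within each cell type, the real split included, only the real one gave as many genes (3345, with 1937 as the highest other). These splits stand for no effect of co-culture in either cell type, not for equal responses of both. The count therefore does not exclude chance for the difference itself, and the spread between replicates may be technical. For the gene lists of this comparison chance was not excluded either, since 10 of the 100 splits gave at least the 12 real calls, and the highest gave 17.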

How the results depend on the processing

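Tests on recovered reads with voom, the share from recovered reads, the ceiling in dESF as well as ESF, the split of the dESF libraries and the reach of 3 times the partner's share were chosen after the data had been seen, and all other alternatives before. The numbers of called genes stayed within 1.5 times the main counts under every pseudocount, scaling and variance setting and under voom, and the exceptions follow. Of the main calls voom kept 93.7% to 95.4% for dESF with ESF, co-cultured dESF and EVT with dESF, 78.8% for co-cultured EVT and 74.7% for the difference of the responses, where it called 17 genes in the opposite direction. P-values here rest on 3 libraries per group, and depth limits statements on genes with a few reads, such as IGFBP1.

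A fold threshold of 2 left 309 genes for dESF with ESF, 313 for co-cultured dESF, 54 for co-cultured EVT, 399 for the difference of the responses and 4238 for EVT with dESF, fewer by construction. A TPM filter of 5 left 5901 for EVT with dESF, since 6612 genes were tested. A fit of only the groups compared left 1279 for co-cultured EVT, with fewer samples behind the spread. With an estimated correlation the list calls numbered 3, 0, 1 and 0 for dESF with ESF, co-cultured dESF, co-cultured EVT and the difference. The estimates exceeded the preset 0.01 for most lists, with 0.839 for mitochondrially encoded mRNAs and 0.352 for syncytiotrophoblast markers. They lay below it for some, such as integrins at -0.006. A higher correlation gives larger camera p-values, so those at the preset correlation may be too small. With fry, which does not compare a list with other genes, the list calls numbered 28, 26 and 23 for dESF with ESF, co-cultured dESF and the difference. With dESF library 1, 2 or 3 for decidualization and the other 2 for co-culture 918, 926 and 927 opposite changes were called, and 749, 806 and 793 the other way round, with fewer samples in each test. EVT RNA in co-cultured dESF was 2.223% from the fixed marker lists, which include genes that dESF express. The share of dESF RNA in co-cultured EVT was 0.004% at a source level of 20 TPM, 0.275% from the fixed lists, 0.034% at a ceiling of 0.5 TPM and 0.03% from summed TPM, and the cause was not tested.

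Leaving out 1 library at a time gave 4492 to 4915 genes for dESF with ESF, 2905 to 3193 for co-cultured dESF, 1511 to 1896 for co-cultured EVT, 2805 to 3211 for the difference and 8692 to 8760 for EVT with dESF. List calls ranged over 12 to 14, 15 to 18, 7 to 12 and 11 to 12 for the first 4 of these. The overlap of both co-culture responses ranged over 335 to 402 genes, the opposite changes over 1149 to 1499, the EVT share over 0.771% to 1.008% and the dESF share from 0 to 0. Among named genes XAF1, TRIM47, MMP11 and NLRC5 lost their calls without 1 library, as given with their values.

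The labels number the replicates but do not say that a number marks a shared culture or day. Deviations of libraries with the same number correlated at -0.069 to 0.146, and in no pair of groups did all 6 samples correlate best with their own number (2 to 4 did), so the numbers were not taken as pairs. With the replicate number as a block, 4837 genes were called for dESF with ESF, 3240 for co-cultured dESF, 1709 for co-cultured EVT, 2907 for the difference and 8875 for EVT with dESF. List calls numbered 14, 16, 9 and 11, the overlap was 334 and the opposite changes 1279. Of the named genes XAF1 and MMP11 lost their calls under the block (adjusted p = 0.07574 and 0.06816).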

Other observations

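The list results in the first paragraph come from tests chosen before the data were examined, as do the counts over other splits, while the choice of the genes named outside the rule, the voom values and all tests of the 3 patterns came after the results were seen.

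Further lists were called by camera at the preset correlation, and each call was lost with an estimated one. With decidualization all 12 tested mitochondrially encoded mRNAs rose (adjusted p = 0.4366 with an estimated correlation), with MT-ND6 up from 787 ± 75.5 to 1677 ± 176 RPM and MT-ND3, MT-ND5 and MT-ND4L up by 0.83 to 0.97 on the log2 scale. In co-culture 0 of the 12 changed (limma adjusted p under 0.05), while 2 fell under voom with median-of-ratios library sizes. Targets of p53 rose for 10 and fell for 2 of 15 (camera adjusted p = 0.03066; adjusted p = 0.2464 with an estimated correlation; 0.06523 without ESF replicate 3), with RRM2B, FDXR, BAX and FAS in front. Histone mRNAs rose for 6 and fell for 0 of 9, and 7 and 0 adjusted over the list alone (adjusted p = 0.08326 with an estimated correlation), among them H2BC5, H2BC8, H2AC6 and H2BC12, in libraries selected for polyadenylated RNA. Genes of cholesterol synthesis and uptake fell for 10 and rose for 2 of 20 (adjusted p = 0.2537 with an estimated correlation), with STARD4, SQLE and LDLR down and TM7SF2 up. In co-cultured dESF heat shock genes fell for 6 and rose for 0 of 13, and 7 and 1 over the list alone (adjusted p = 0.2108 with an estimated correlation), with HSPH1, HSPD1, HSP90AB1 and HSPA8 at -0.47 to -0.31.

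CGA, chosen after its values were seen, rose with decidualization before any co-culture, from 0.0824 ± 0.143 to 11.2 ± 1.74 RPM (limma 0.82 ± 0.16, adjusted p = 0.001044, but 0.2374 at a pseudocount of 5). CGB5 and HSD3B1, which EVT also express, stood at 0.0179 ± 0.0311 and 0.0 in the same dESF libraries.

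Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes for each comparison. The real counts and the highest of the other splits were 5138 and 0 for dESF with ESF, 3628 and 0 for co-cultured dESF, 2130 and 5 for co-cultured EVT, and 8910 and 0 for EVT with dESF. For the list tests they were 14 and 11, 16 and 11, and 9 and 8 for the first 3 of these. For the genes that both cell types changed in the same direction, 1 of 100 splits gave as many as the real 454, and the highest other gave 2. Regrouped libraries call few genes in either cell type, so this count does not tell whether the lists share more genes than independent lists would.

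The first pattern was that genes high in EVT and scarce in ESF, among them HSD3B1, NOTUM and gonadotropin chains, were read in co-cultured dESF. Reads of near-identical copies are not the whole cause, since 37 of 39 such genes outside families of copies were higher than in single-cultured dESF. A fixed share of the mean EVT profile is not the whole cause either, since 8 genes lay over 2-fold from the median of 1.03% of the co-cultured EVT level, AADACL3 at 3.77% and NOTUM at 2.56% among them. EVT RNA or cells carried over into the dESF libraries is a candidate explanation. Of the 45 genes, 27 had their co-cultured libraries in the order of the median of the others, beside a 95th percentile of 12 computed for independent genes. The genes are not independent, and a joint response of dESF would order the libraries alike too, so this count does not separate it from carry-over. Of the 37 genes at most at 0.1 TPM in dESF as well, 22 had that order (95th percentile 10 for independent genes), 31 of 32 outside families of copies were higher, and 8 lay over 2-fold from the median. Carried cells that differ from the mean EVT, and expression of some of these genes by dESF, stay open and were not tested.

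The second pattern was that decidualization changes were followed by opposite changes in co-culture, with CXCL12, COL14A1 and THBS2 rising after a fall. The pattern is one of direction and not of a return to the ESF level. CXCL12 and COL14A1 rose past it (273.9% and 191.7% of the fall), and the changes of MMP3 and POSTN were mostly kept (8.9% and 10.3% undone). The shared dESF libraries would give a covariance of -0.009 in simulations of unchanged groups, and -0.046 was observed, while the Pearson r (-0.257, with -0.503 simulated) and the share of equal signs (42.9%, with 33.3%) showed less opposition than in the simulations. With the dESF libraries split so that none was in both comparisons the covariance was still -0.041 to -0.037, so noise of the shared libraries is not the whole cause. What all 3 dESF libraries had in common, such as a day or a culture, stays open. Without genes within reach of the median EVT share 1450 of 1457 opposite changes were left. Genes that fell in co-culture could not be left out this way. Genes carried over at a higher share than the median stay in that count, so it does not tell how many opposite changes came from EVT RNA. Over the 4 other scalings the lowest ratio to independent lists was 1.71. Of 100 splits 5 gave as many opposite changes, the real one included, with 3313 as the highest other. The 4 others kept 7 to 9 of the 9 libraries beside their own group (median over all splits 5) and so mostly exchanged whole groups, whose real differences return as opposite changes. This count therefore does not exclude chance and is no measure of it. In 20 simulations of unchanged groups at most 1 gene was called in opposite directions. Unchanged groups give few calls in either comparison, so this number does not bear on real changes measured against shared dESF libraries. That these genes differed between co-cultured and single-cultured dESF was tested, but what in the co-culture brought the difference was not.

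The third pattern was that the levels in the table were set by lengths of other genes. Lengths behind the values had a Spearman correlation of -0.008 with the genes' own spans, so the TPM were not scaled by each gene's own span. Lengths joined in another order would give this wherever reads were counted, so it does not tell over which region they were counted. A file whose unit is not quite what its name says is a candidate explanation: for 3112 genes whose length matched the span of 1 other gene, the table row followed the genomic order of that other gene with a Spearman correlation of 0.954. Lengths joined to the genes in another order may thus stand behind the TPM, with 31 bp for KANK4 (own span 82436 bp) and 173835 bp for GAPDH (own span 4448 bp). No biological explanation was tested.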
